A study of Homo sapiens with 15 samples.

How the data were processed

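Gene expression was measured by RNA sequencing of 15 libraries of WI-38 cells, a line of human fetal lung fibroblasts with a limited number of divisions in culture. Per the labels, RNA was extracted with Trizol and the libraries were prepared by standard Illumina protocols. The libraries fall into 5 groups of 3, taken from the sample titles and treatment labels: a PD30 control, a PD45 control, PD45 cells with siSRC2, PD45 cells with siSRC4 (read as 2 siRNAs from the titles, since the treatment label is the same), and PD45 cells with GW8510. PD is read as population doublings, and the labels give the time points as cell generations. Every group received a lipofection reagent, and every group but the GW8510 one received DMSO. By the labels, the compound and the absence of DMSO can therefore not be separated in the GW8510 comparison. The PD45 control and the GW8510 group also carry the label NC, read as a negative-control siRNA, and the PD30 control does not. Passage and NC can therefore not be separated in the comparison of PD30 with PD45.

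The submitters' processing notes name CASAVA, HISAT2, StringTie, RSEM, DESeq2 and edgeR, without roles or versions that could be used here. The same notes name the build GRCm38, a mouse assembly, while every gene identifier in the deposited tables is a human Ensembl identifier, so no coordinates are given. The 4 deposited tables each compare one group with the PD45 control. Per the file headers, each row holds the authors' fold ratio, the authors' log2 fold change, the authors' p-value and adjusted p-value, the expression signal of 3 libraries per group and the authors' mean signal per group. The deposited signal is a normalized expression value with 2 decimals per gene and library, and the file headers do not say whether it is TPM or FPKM. Read depth per library is therefore unknown, and no counting interval or detection floor is given. In the 4 tables together, 4872 genes were present, 22 of them in all 4. The values of the PD45 control libraries were identical in every table that shared a gene.

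Each table holds only genes past an adjusted p of 0.05 and a fold change of at least 1.5 in either direction. Genes outside a table were not used here, so a gene missing from a table is not shown to be unchanged. The tables were matched to groups by the library names in their columns. In the table whose mean column is titled siSRC2 the library columns are named siSRC4, and in the table whose mean column is titled siSRC the library columns are named siSRC2. The library names were followed for both. Because the deposited adjusted p is the Benjamini-Hochberg value, its ratio to the p in the first row gives the number of genes the authors tested. This assumes that the first row holds the smallest p of all tested genes. The rank of the last listed gene follows from that number. The median difference between the authors' log2 fold change and the log2 ratio of mean signals was 0.02 for PD30, 0.12 for GW8510, -0.05 for siSRC2 and -0.04 for siSRC4. A signal ratio for GW8510 thus lies below the authors' fold change by that median shift.

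From the deposited signals, group means, SD (n = 3) and ratios of mean signals were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The listed genes of each table were re-tested with limma 3.58.1 in R 4.3.3 on log2(signal + 1), with a mean-variance trend, for genes with a mean signal of at least 1. Differences on that scale understate the change of genes with low signal. The re-test is conditional on the authors' selection and describes how far the deposited signals carry each call, and it is no independent evidence of a difference. Each fit used the 6 libraries of its comparison. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

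Before the data were examined, 38 gene lists with 808 symbols were fixed, of which 806 matched an identifier by symbol, for 783 distinct genes. The 2 unmatched symbols are older names of genes that the lists already hold. For each list with at least 5 listed members, the direction of the members was compared with that of all other listed genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists tested (22 for PD30, 15 for GW8510, 1 for siSRC2 and 2 for siSRC4). Over-representation of a list, added after the data were seen, was tested by the hypergeometric distribution against the number of genes the authors tested, and adjusted over 38 lists. Both tests, and the simulation of directions from GC content, treat genes as independent although they are not, so their p-values may be too small. Tests over all genes, rank-based list tests and counts adjusted over the list alone need genes outside the tables and were not run.

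For each pair of comparisons, the genes present in both tables were counted by direction, with an exact binomial interval at 95%, which treats genes as independent although they are not. All 4 comparisons share the same 3 PD45 control libraries. Unchanged groups were therefore simulated in 100 draws, in which 2 groups of 3 were compared with the same 3 simulated controls. Each gene took its mean from the PD45 control and its spread from the control and both groups of the pair. The covariance of the log2 fold changes was set beside the simulated one. For GW8510 with PD30 a bound was added after the data were seen. It counts 1% of the genes that each table implies at an adjusted p under 0.01 as false and going the same way, and gives the others independent directions. With 3 control libraries the controls could not be split into parts of at least 2. Genes with opposite directions in 2 treatments were tested with limma between the 2 treatments directly, without a signal minimum and adjusted over all genes shared by the pair. GC content and length of the longest transcript per gene came from the GENCODE annotation, with a value for 98.6% to 99.8% of the genes of each table. The direction expected for a pair was computed within 9 classes of GC content and transcript length, by 10000 permutations. The permutation p is one-sided, for a share at least as large as the observed one.

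Apart from JAK2 and the genes of the closing observations, the genes named in the text follow a rule fixed before the data were examined. It takes SRC, then from each fixed list with at least 3 listed members the 2 with the smallest adjusted p in the majority direction and the 1 in the minority direction, in order of listed members, until 24 genes are named. It adds the 4 largest rises and 4 largest falls among genes whose groups do not overlap and whose higher mean signal is at least 5. Some genes that the rule takes are not reported here. For pairs of comparisons it takes the 5 genes per direction whose smaller log2 fold change of the 2 comparisons is largest in size. Genes with near-identical relatives, overlapping genes and antisense genes are called uncertain, since the counting and its strand setting are not given in the sources used here.

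Alternatives covered the thresholds, the pseudocount (0.1 in place of 1), the filter on low signal, each library left out in turn, a replicate block and one fit over all groups. Same-numbered siSRC4 and control libraries deviated together, with correlations of 0.122, 0.107 and 0.136 across 1170 genes, all above the bound of 0.1 set for pairing. By that rule the replicate numbers pair that comparison, on the evidence of the signals alone, since the labels give no shared batch or day.

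The procedures were tested on simulated data. With changes spiked into the PD30 signals (2845 genes), limma recovered 68.7% of 1.5-fold, 89.6% of 2-fold and 90.9% of 4-fold changes and called 8 unchanged genes. The same shares were 74.6%, 85.1% and 90.9% for GW8510 (1845 genes, 5 unchanged called), and 75.7%, 83.8% and 88.9% for siSRC2 (331 genes, 5 unchanged called). For siSRC4 (1280 genes) they were 67.2%, 82.1% and 84.8%, with 7 unchanged genes called. The direction test recovered the changed list in 100% of 100 draws on the PD30 table and called another list in 3%. These draws gave each other gene an independent direction, whereas members of a real list may change together. The 3% is therefore not shown to hold for the real lists. The recovered number of tested genes was exact for all 4 tables, which the formula assures because the simulation always listed the smallest p. Whether the deposited tables list it was not tested. The permutation within classes, run for PD30 and GW8510 on 600 genes, called 5% of 20 draws that held a GC trend alone and 100% of 20 draws with a shared direction added.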

Results

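The data are transcriptomes of WI-38 human lung fibroblasts at PD30 and PD45, with the PD45 cells described as senescent. At PD45, SRC was targeted with siSRC2 or siSRC4, read from the sample names as 2 siRNAs, or the cells received GW8510, a kinase inhibitor known as an inhibitor of cyclin-dependent kinases. SRC encodes a non-receptor tyrosine kinase. The 15 libraries form 5 groups of 3, and each comparison is against the PD45 control. The study asked about rejuvenation by GW8510 and about pathways that include SRC, PAK and JAK kinases. Neither the dose nor the duration of GW8510 is in the labels. Expression is given as the deposited normalized signal, as mean ± SD over the libraries of a group (n = 3). Fold values below are ratios of mean signals unless the authors' deposited table is named. Read depth is unknown.

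The knockdown target was lower with both siRNAs. SRC signal was 19.8 ± 0.766 in the PD45 control, 11.3 ± 0.580 with siSRC2 and 10.8 ± 1.16 with siSRC4, or 57.0% and 54.6% of the control. In each case all 3 knockdown libraries lay below all 3 control libraries, where the smallest two-sided exact permutation p that 3 against 3 allows is 0.1. The limma re-test gave an adjusted p of 0.000184 for siSRC2 and 0.000586 for siSRC4. The authors' deposited table gave log2 fold changes of -0.81 with siSRC2 and -0.90 with siSRC4. With 3 against 3 libraries no difference in residual SRC between the siRNAs could be called (two-sided exact permutation p = 0.7). SRC was not among the genes listed for PD30 or for GW8510.

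**Figure D1:**
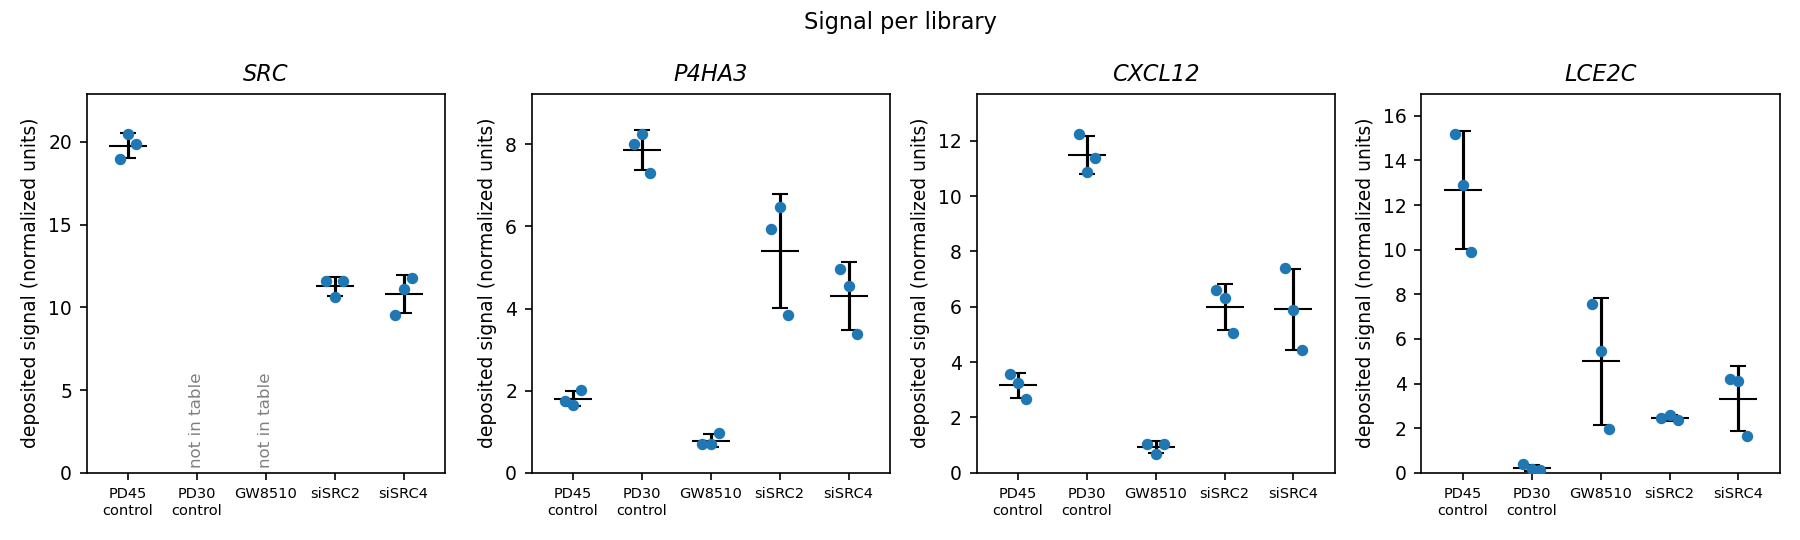
Deposited signal per library (points) with group mean and SD (bars, 3 libraries per group) for SRC and for P4HA3, CXCL12 and LCE2C, which are listed in all 4 comparisons. SRC was 19.8 in the PD45 control and 11.3 and 10.8 with the siRNAs, and groups in whose table SRC is not listed are marked.

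The comparison of PD30 with PD45 asks how the younger culture differs from the senescent one. PD30 cells held far more transcript of the division machinery, and less of p53 targets and of cholesterol synthesis enzymes. All 40 genes of the mitosis list were listed as higher at PD30, as were 38 of 40 DNA replication genes and 17 of 20 homologous recombination genes. Of the 28 p53 targets, 19 were lower and 1 was higher, and 17 of 24 cholesterol synthesis genes were lower with none higher. The authors' deposited table lists 2845 genes for this comparison, 1531 higher and 1314 lower at PD30. In 2662 of them the libraries of the groups did not overlap, where 10% would by chance for genes not selected. Fisher's exact test of direction gave adjusted p-values of 3.28e-10 for mitosis, 5.96e-10 for replication, 0.000121 for recombination, 4.60e-05 for p53 targets and 1.37e-05 for cholesterol synthesis.

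Among mitotic genes, KIF20A, a kinesin of cytokinesis, had a signal of 29.9 ± 1.39 at PD30 and 1.84 ± 0.152 at PD45, a ratio of 16.2. CDC20, an activator of the anaphase-promoting complex, stood at 53.3 ± 2.70 at PD30, a ratio of 13.3. HMMR, a spindle-associated hyaluronan receptor, was 7.76-fold higher, and 12.4-fold higher in the authors' deposited table. Of nucleotide synthesis genes, RRM2 was 8.14-fold higher (56.6 ± 2.81 against 6.96 ± 0.986) and TK1 8.21-fold higher (71.4 ± 3.57 against 8.70 ± 0.835). The Fanconi anaemia repair genes FANCI and FANCG were 3.01-fold and 3.35-fold higher. Among cell-cycle kinase genes, 8 were higher and 2 lower, and CCNA2, a cyclin of S phase and mitosis, rose 6.60-fold. CDKN2C, a CDK inhibitor, was also higher, by 6.86-fold, and the direction of this list did not differ from other listed genes (Fisher's exact test, adjusted p = 0.175).

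CDKN1A, which encodes the p53-induced CDK inhibitor p21, had a signal of 703 ± 36.1 at PD30 and 2154 ± 92.0 at PD45, a 3.06-fold lower level. RRM2B, the p53-inducible subunit of ribonucleotide reductase, was 2.68-fold lower at PD30, while PLK2 was the 1 p53 target that was higher (83.7 ± 5.28 against 46.0 ± 4.55). Of 18 senescence markers, 9 were lower and 4 higher at PD30. IGFBP7, a secreted growth factor-binding protein, fell to 183 ± 8.16 from 642 ± 70.5, and LMNB1, a nuclear lamin lost in senescent cells, was 8.34-fold higher. The direction of this list as a whole did not differ from other listed genes (adjusted p = 0.163, Fisher's exact test). The list also holds markers lost in senescence, such as LMNB1, so a test of direction says little about it. Of its 18 genes 13 were listed, where 2.76 were expected (hypergeometric test, adjusted p = 6.31e-07). For PD30, 13 of the 38 lists were over-represented at an adjusted p under 0.05. MSMO1 and DHCR7, enzymes of late sterol synthesis, were 4.28-fold and 2.57-fold lower. The mitochondrially encoded genes had 6 of 13 members listed, all lower at PD30 (Fisher's exact test, adjusted p = 0.0354). Their signals ran from 1.54-fold to 1.78-fold lower, and no member reached 2-fold. Against the direction expected from their GC contents the list did not pass (adjusted p = 0.0754, simulation of directions).

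Several lists leaned one way without passing the direction test. In the amino acid and ER stress list, 12 genes were higher and 2 lower (Fisher's exact test, adjusted p = 0.0511). PHGDH and PSAT1, enzymes of serine synthesis, were 4.75-fold and 3.72-fold higher, and DNAJB9, an ER chaperone, was 2.11-fold lower. Collagen and matrix genes were higher for 10 and lower for 2 members (adjusted p = 0.0985, Fisher's exact test). COL3A1 was 3.28-fold and COL6A3 2.41-fold higher, and COL11A1 1.81-fold lower. Interferon-stimulated genes split alike, 10 against 2, with the same adjusted p, but 6 of these 12 were below the signal minimum of the limma re-test. IFIT1 was 4.02-fold and GBP2 3.69-fold higher, and TRIM22 2.90-fold lower. Lysosome and autophagy genes were lower for all 5 listed members (adjusted p = 0.0576, Fisher's exact test).

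Among genes whose higher mean signal was at least 5, the largest rise was that of RASL12, a Ras-like small GTPase gene (5.02 ± 0.181 against 0.277 ± 0.0379). The largest falls under the same limit were those of the pseudogene CEACAMP10, LCE2C, HCLS1 and PSG1. HCLS1, a cortactin relative of blood cells, stood at 0.273 ± 0.0208 against 7.75 ± 0.272. CEACAMP10, LCE2C and PSG1 belong to families of near-identical genes and their levels are uncertain. Of 2258 listed genes that entered the limma re-test, 2197 passed in the authors' direction, and the 30 named genes had adjusted p-values from 2.90e-08 to 0.00253. PD30 and PD45 also differ in the control siRNA, and the labels do not let passage and siRNA be separated.

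**Figure D2:**
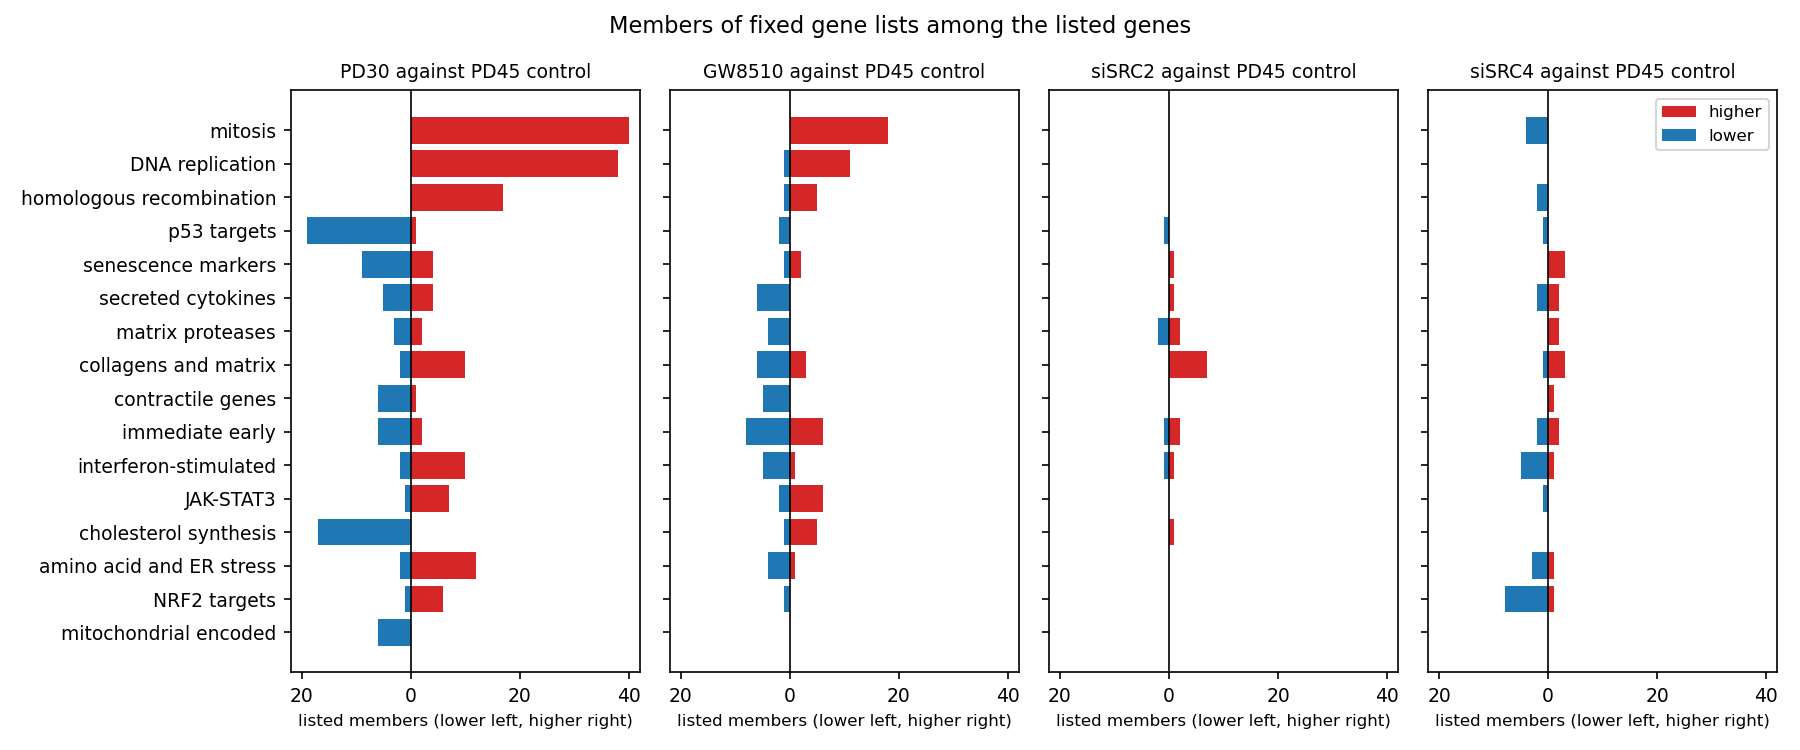
Number of listed members of 16 fixed gene lists that were higher (red, right) or lower (blue, left) than in the PD45 control, per comparison. The mitosis list has 40 members higher at PD30, 18 higher with GW8510 and 4 lower with siSRC4.

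The GW8510 comparison asks what the kinase inhibitor changes in PD45 cells. With GW8510, mitosis and DNA replication genes were in part higher. Of the mitosis list, 18 of 40 genes were listed and all were higher, and of the replication list 11 were higher and 1 lower. Immediate-early genes and JAK-STAT3 genes were listed more often than the size of the lists gives. Of 30 secreted cytokine genes 6 were listed, all lower, and of 23 matrix proteases 4, all lower, and neither list was over-represented (hypergeometric test, adjusted p = 0.399 and 0.597). The authors' deposited table lists 1845 genes, 715 higher and 1130 lower with GW8510. The libraries of the groups did not overlap in 1671 of them, against 10% by chance for genes not selected. The direction of mitosis genes (Fisher's exact test, adjusted p = 5.11e-07) and of replication genes (adjusted p = 0.00165) differed from the other listed genes, and no other list passed.

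FOXM1, a transcription factor of mitotic genes, had a signal of 7.52 ± 1.05 with GW8510 and 3.33 ± 0.441 in the control, a ratio of 2.26. BIRC5, the chromosomal passenger protein survivin, was 2.88-fold higher (7.33 ± 1.18 against 2.55 ± 0.204). MYBL2, a transcription factor of the dividing cell, was 5.47-fold higher (8.03 ± 1.41 against 1.47 ± 0.163). RRM2 and TK1 rose 2.75-fold each, to 19.1 ± 2.32 and 23.9 ± 1.71, below the 56.6 and 71.4 of PD30 cells. RRM1, the large subunit of ribonucleotide reductase, fell to 12.2 ± 1.26 from 20.2 ± 1.82. The listed mitosis genes had a median ratio of 1.70, against 7.29 for this list at PD30. In the limma re-test 14 of the 18 passed, and 2 were below its signal minimum. FANCA, a Fanconi anaemia gene, was 1.72-fold higher, in a recombination list with 5 genes higher and 1 lower. The direction of that list did not pass (Fisher's exact test, adjusted p = 0.106), nor did that of cell-cycle kinase genes, 5 higher and 1 lower, with the same adjusted p. CCND3 and CCND2, D-type cyclins, were both 1.47-fold higher, and CDK19, a Mediator-associated kinase, was 2.07-fold lower.

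Of 29 immediate-early genes 14 were listed, where 3.44 were expected from the number tested (hypergeometric test, adjusted p = 2.66e-05), and their directions were mixed. EGR1, a transcription factor induced by growth factors, fell to 3.84 ± 0.307 from 14.8 ± 3.47. DUSP6, a phosphatase induced by ERK signalling, was 1.88-fold lower, and FOSL2, an AP-1 subunit, was 1.54-fold higher. JAK-STAT3 genes had 6 higher and 2 lower among 19 (expected 2.25, hypergeometric test, adjusted p = 0.0109). SOCS3, a STAT3-induced feedback inhibitor, was 1.98-fold higher and the cytokine receptor gene LIFR 1.60-fold higher. The shared receptor chain IL6ST was 1.85-fold lower, and JAK2 was lower at 0.943 against 1.72. No member of the PAK list or of the SRC family list was listed for GW8510.

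Matrix genes went both ways, with 3 higher and 6 lower. TNC and FN1, which encode tenascin C and fibronectin, were 3.18-fold and 2.66-fold lower, and COL3A1 was 1.76-fold higher (202 ± 29.7 against 115 ± 6.82). MMP1, the interstitial collagenase, was 6.07-fold lower (3.92 ± 0.841 against 23.8 ± 8.15), and AREG, an EGF receptor ligand, 7.55-fold lower. Of the 6 listed cytokine genes 4 passed the limma re-test and 2 were below its signal minimum. Neither the cytokine list (Fisher's exact test, adjusted p = 0.188) nor the matrix list (adjusted p = 1) differed in direction from the other listed genes, and the 4 proteases were too few to test. Cholesterol synthesis genes had 5 higher and 1 lower (adjusted p = 0.106, Fisher's exact test). LSS was 1.44-fold higher and TM7SF2 1.95-fold lower. Of 6 listed ageing regulators, 5 were lower, among them PRKAA1, a catalytic subunit of AMPK, and RICTOR, an mTORC2 component, by 1.67-fold and 2.54-fold. IRS2, an insulin receptor substrate, was 1.74-fold higher. This list passed neither the test of direction (Fisher's exact test, adjusted p = 0.622) nor that of over-representation (adjusted p = 0.195), and 1.34 of the 6 would have been higher at the rates of their GC contents.

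Among genes whose higher mean signal was at least 5, the largest rises included PIK3R2, a regulatory PI3-kinase subunit, whose libraries spread widely (28.1 ± 17.3 against 3.38 ± 2.06). SLC14A1, a urea transporter, was 4.33-fold lower. The unnamed genes ENSG00000272540, ENSG00000278996 and ENSG00000280852 also reached the extremes under that limit, and their signals are uncertain because they may share reads with other genes. Listed genes that rose and fell differed in composition. Genes higher with GW8510 had a median transcript GC content of 55.1% and those lower of 41.6%. Median transcript length was 2844 bases for genes higher and 4685 for genes lower, and the gene lists were not tested against length. Mitosis genes listed for GW8510 had a median of 48.2% and those not listed 40.2%. At the GC contents of the 18 mitosis genes, 7.16 would have been higher at the rates of all listed genes, and for the 12 replication genes 5.85. Both lists stayed above that expectation (adjusted p = 0.00300 and 0.0120, simulation of directions), and the 6 cytokine genes did not differ from theirs (adjusted p = 0.597). In the limma re-test 1551 of 1625 genes passed in the authors' direction, and the 32 genes that the naming rule takes had adjusted p-values from 7.33e-06 to 0.0347.

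The siSRC2 comparison asks what knockdown of SRC with that siRNA changes at PD45. With siSRC2, 7 of 37 collagen and matrix genes were listed, all higher. Other lists had at most 4 listed members, reached by the matrix proteases with 4 of 23, and genes not listed are not shown to be unchanged. COL6A3 rose 1.77-fold, to 1044 ± 80.2 from 591 ± 41.4, and COL3A1 1.96-fold, to 225 ± 25.3 from 115 ± 6.82. PLAT, the tissue plasminogen activator, rose 2.70-fold, to 362 ± 17.8 from 134 ± 3.50, while PLAU, the urokinase, fell 1.82-fold, to 231 ± 2.88 from 420 ± 36.9. The authors' deposited table lists 331 genes, 173 higher and 158 lower, 300 of them with groups that did not overlap (10% by chance for genes not selected). The direction of the matrix list differed from that of the other listed genes (Fisher's exact test, adjusted p = 0.0153), and it was the only list with enough members to test.

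MMP14, a membrane-bound collagenase, was higher at 496 ± 69.4 against 331 ± 39.8, and the protease list split 2 against 2. NR4A2 and NR4A3, orphan nuclear receptors induced early after stimulation, were 2.28-fold and 1.76-fold higher, and KLF2, a transcription factor responsive to flow, was 1.93-fold lower. P4HA3, a collagen prolyl hydroxylase subunit, was higher at 5.41 ± 1.39 against 1.81 ± 0.184, and SCG2, a secretory granule protein, 2.89-fold higher. The unnamed gene ENSG00000268643 had the largest rise among genes whose higher mean signal was at least 5. SFXN3, a mitochondrial serine transporter relative, fell 2.18-fold, to 25.5 ± 0.769 from 55.6 ± 3.62. The falls of LCE2C, LCE2A and PSG1 are uncertain because of near-identical relatives. Median GC content was 47.5% for genes higher and 51.3% for genes lower, and 53.2% for the 7 matrix genes, of which 3.29 would have been higher at the rates of their GC contents (adjusted p = 0.0108, simulation of directions). Direction with siSRC2 followed transcript length more closely than GC content, with a median of 5223 bases for genes higher and 2698 for genes lower, and the matrix list was not tested against length. In the limma re-test 296 of 310 genes passed, and the 16 named genes had adjusted p-values up to 0.0179.

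The siSRC4 comparison asks the same with the second siRNA. NRF2 target genes leaned lower, with 9 of 20 listed, 8 of them lower, without passing the direction test. AKR1C1, an aldo-keto reductase, fell 2.59-fold, to 13.2 ± 1.70 from 34.2 ± 3.79, and TXNRD1, a thioredoxin reductase, 1.71-fold, to 203 ± 29.7 from 348 ± 33.9. The level of AKR1C1 is uncertain because of near-identical relatives. HMOX1, heme oxygenase, was the 1 member that was higher (38.1 ± 3.84 against 21.8 ± 3.23). The list was over-represented (1.75 expected, hypergeometric test, adjusted p = 0.000779), and for direction Fisher's exact test gave an adjusted p of 0.0966. The authors' deposited table lists 1280 genes, 571 higher and 709 lower, 1136 of them with groups that did not overlap (10% by chance for genes not selected).

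Interferon-stimulated genes had 5 lower and 1 higher (Fisher's exact test, adjusted p = 0.234). SAMD9L was 1.64-fold lower and MX1, an antiviral GTPase, 1.81-fold higher. No mitosis gene was higher and 4 were lower, among them AURKA, a mitotic kinase, by 1.73-fold, and ANLN, a cytokinesis scaffold, by 1.56-fold. Of the secreted cytokines 2 were higher and 2 lower, and IL6 was 1.89-fold and CXCL12 1.87-fold higher. COL8A1 and COL4A1 were 1.74-fold and 1.67-fold higher, and POSTN, which encodes periostin, 2.26-fold lower. Adhesion genes split 2 against 2, with the integrin genes ITGA3 and ITGB3 1.82-fold and 1.59-fold higher and CAV1, which encodes caveolin, 1.93-fold lower. The glucose transporter gene SLC2A1 was 1.71-fold lower. The collagen prolyl hydroxylase genes P4HA1 and P4HA2 went apart, 1.60-fold lower and 1.71-fold higher. ATF3 and SLC7A11, both induced by amino acid stress, were 1.91-fold and 2.06-fold lower, and TRIB3 1.56-fold higher. FOSL2 and NR4A2 were 1.68-fold and 1.73-fold higher.

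SEMA7A, a membrane-anchored semaphorin, rose 3.46-fold with siSRC4, to 140 ± 10.0 from 40.5 ± 4.29. SLC37A2, a sugar phosphate exchanger, and PPFIA3, a liprin, rose 3.58-fold and 2.59-fold, as did the unnamed gene ENSG00000269910. FABP4, a fatty acid-binding protein, fell 3.10-fold, to 29.2 ± 2.11 from 90.6 ± 1.80, and DKK2, a secreted WNT modulator, 3.34-fold. The antisense gene RIPOR3-AS1 and LCE2C also fell, and both levels are uncertain. Median GC content was 55.4% for genes higher and 41.0% for genes lower with siSRC4. The 9 listed NRF2 targets had a median of 44.8%, and 3.96 of them would have been higher at the rates of their GC contents (1 observed, adjusted p = 0.0300, simulation of directions). In the limma re-test 1096 of 1170 genes passed in the authors' direction, and the 33 genes that the naming rule takes had adjusted p-values from 4.09e-05 to 0.0293.

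**Figure D3:**
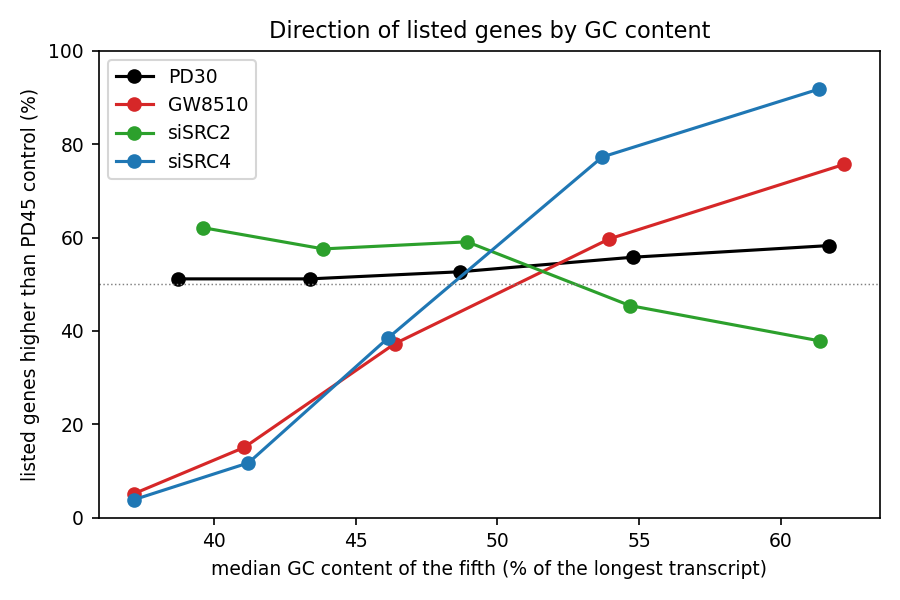
Percentage of listed genes that were higher than the PD45 control (vertical axis) in 5 equal bins of transcript GC content (horizontal axis, median per bin) for each comparison. From the lowest to the highest bin the share goes from 5.19% to 75.7% with GW8510 and from 3.91% to 91.8% with siSRC4, and from 51.2% to 58.3% for PD30.

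Whether a treatment moved PD45 cells towards the PD30 level was asked of genes listed in both comparisons. With GW8510, 438 of 606 shared genes (72.3%, 95% exact interval 68.5% to 75.8%) changed in the direction of PD30. The 606 were 21.3% of the genes listed for PD30 and 32.8% of those listed for GW8510. MYBL2 was among the largest shared rises, at 12.7 ± 2.40 in PD30, 8.03 ± 1.41 with GW8510 and 1.47 ± 0.163 in the control. All 18 shared mitosis genes and 11 of 12 shared replication genes went the same way, and so did all 5 shared JAK-STAT3 genes. All 3 shared amino acid stress genes went opposite ways. Of the 28 p53 targets only 2 were listed for GW8510 (3.32 expected), both lower as at PD30. Of the 3 shared cholesterol synthesis genes 1 went the same way and 2 opposite ways, and the 6 shared matrix genes split 3 against 3. CXCL12, a chemokine, was 11.5 ± 0.693 at PD30 but 0.927 ± 0.205 with GW8510, against 3.16 ± 0.459 in the control. Of the 168 genes with opposite directions, 167 also differed in a direct limma test at an adjusted p of 0.05, which choosing them by opposite calls nearly assures. Of the 438 with the same direction, 206 still differed between PD30 and GW8510 in that test.

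With siSRC2, 124 of 153 shared genes (81.0%, 73.9% to 86.9%) went towards PD30, including P4HA3, at 7.86 ± 0.490 in PD30 and 5.41 ± 1.39 with siSRC2. ADAMTS9, a matrix protease, and FGL2, a fibrinogen-like protein, were also higher in both, at 2.38 ± 0.264 and 6.15 ± 0.638 in PD30. All 4 shared matrix genes went towards PD30. CDKN3, a cell-cycle phosphatase, went the other way, with 30.2 ± 2.70 at PD30, 5.74 ± 0.942 in the control and 2.87 ± 0.725 with siSRC2. With siSRC4, 250 of 412 shared genes (60.7%, 55.8% to 65.4%) went towards PD30. In simulated unchanged groups 66.0% of these genes had the same sign, without a fold threshold. Of the few simulated genes past that threshold in both, 98.7% had it for siSRC4, 97.4% for GW8510 and 93.9% for siSRC2. None of the observed shares is therefore by itself evidence of a move towards PD30. DKK2 was lower in both, while AKR1C1, whose level is uncertain, went opposite ways, higher at PD30 and lower with siSRC4 (13.2 ± 1.70 against 34.2 ± 3.79). All 4 shared mitosis genes and all 3 shared senescence markers went away from PD30 with siSRC4. The 1 senescence marker shared with siSRC2 also went away from PD30, and the 3 shared with GW8510 went towards it.

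**Figure D4:**
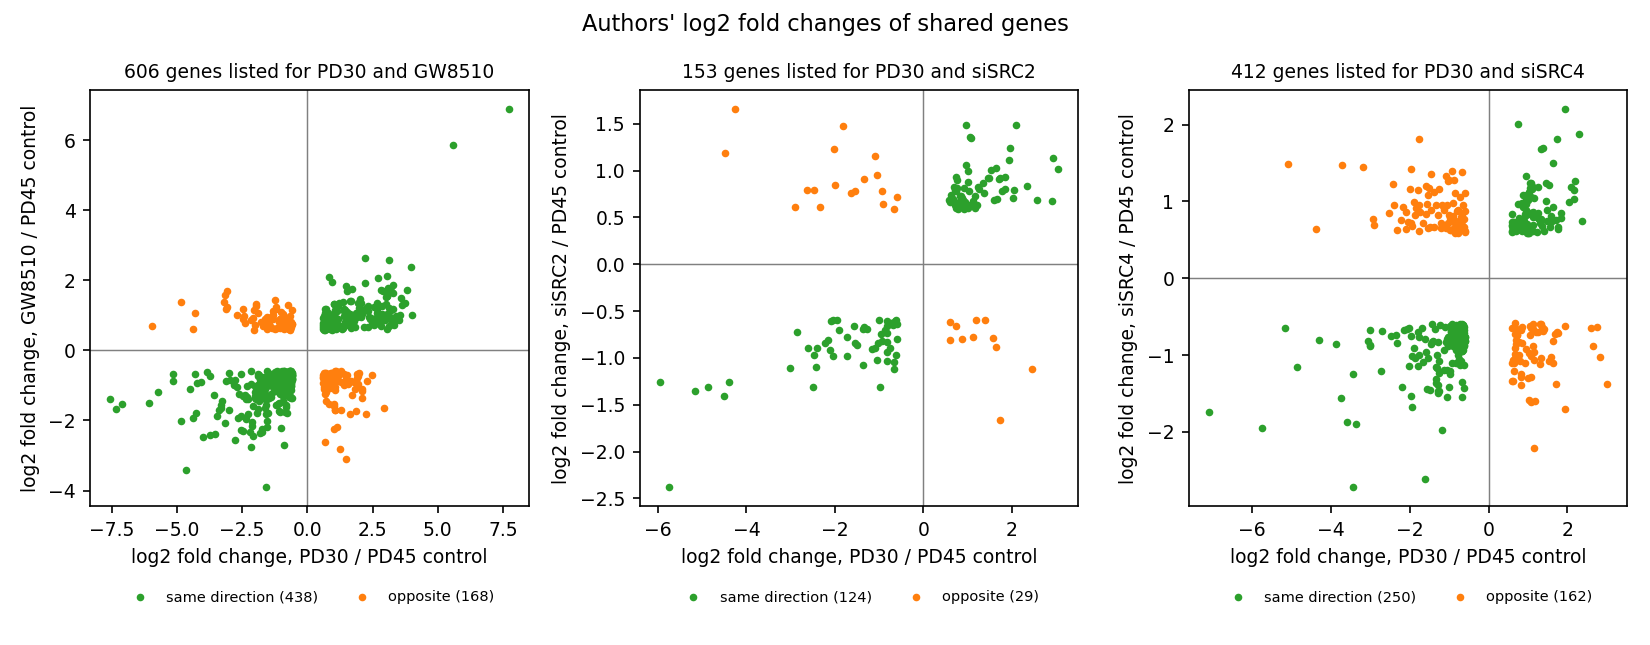
Log2 fold changes from the authors' deposited tables for genes listed at PD30 (horizontal axis) and with each treatment (vertical axis), all against the PD45 control. Genes with the same direction (green) number 438 of 606 for GW8510, 124 of 153 for siSRC2 and 250 of 412 for siSRC4.

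The 2 siRNAs against SRC shared 104 listed genes, of which 86 (82.7%, 74.0% to 89.4%) went the same way. P4HA3 rose with both, to 5.41 ± 1.39 and 4.31 ± 0.820, and SLC2A12, a glucose transporter, fell with both, to 1.14 ± 0.204 with siSRC2 from 2.24 ± 0.514. Of the siSRC2 genes 31.4% were listed for siSRC4, and of the siSRC4 genes 8.13% for siSRC2. For siSRC4, 4 of 37 matrix genes were listed, 3 higher and 1 lower, and 2 matrix genes were listed for both siRNAs, in the same direction. No NRF2 target was listed for siSRC2, against 9 of 20 for siSRC4. For these lists the siRNAs thus did not give the same listed genes, and the cause was not tested. GW8510 and siSRC4 shared 322 genes, 226 of them with the same direction (70.2%, 64.9% to 75.1%). Within classes of GC content and length 68.0% were expected (permutation p = 0.156), and of 40 genes changed at least 2-fold in both 65.0% went the same way (48.3% to 79.4%), so no shared direction beyond composition was found. ITGA8, an integrin subunit, fell with both, to 2.08 ± 0.129 and 4.39 ± 0.463. BAMBI, a TGF-beta pseudoreceptor, went apart, 1.98-fold higher with GW8510 and 2.27-fold lower with siSRC4.

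GW8510 and siSRC2 shared 103 genes, and only 37 of them went the same way (35.9%, 26.7% to 46.0%), so that 66 went opposite ways. All 66 also differed in the direct limma test at an adjusted p of 0.05, which choosing them by opposite calls nearly assures. PLAT was 57.4 ± 10.7 with GW8510 and 362 ± 17.8 with siSRC2, against 134 ± 3.50 in the control. KRT19, a keratin gene, went to 235 ± 27.0 and 73.6 ± 1.40 from 135 ± 12.7, and GPRC5A, a retinoic acid-induced receptor, to 108 ± 4.96 and 26.0 ± 3.41 from 39.6 ± 3.26. COL3A1 rose with both.

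The shared control libraries give agreement with no effect at all. In simulated unchanged groups, 65.6% to 66.2% of genes had the same sign, but at most 1.55 genes per pair passed the fold threshold in both. Of those few, 90.9% to 98.8% had the same sign, above every observed share. The observed covariance of log2 fold changes, enlarged by choosing genes past the fold threshold, was 1.23 for PD30 with GW8510 (0.0138 simulated), 0.875 for PD30 with siSRC2 (0.0122) and 0.310 for PD30 with siSRC4 (0.0144). It was 0.478 for the 2 siRNAs (0.0170), 0.237 for GW8510 with siSRC4 (0.0189) and -0.26 for GW8510 with siSRC2 (0.0183). The observed values use the authors' log2 fold changes and the simulated ones log2(signal + 1), which understates changes of genes with low signal. Their sizes are therefore not on the same scale. Independent lists of these sizes give another expectation. PD30 and GW8510 had 177 genes higher and 261 lower in both, where 70.3 and 95.3 were expected. PD30 had 68 and 56 with siSRC2 (21.1 and 16.5 expected) and 108 and 142 with siSRC4 (59.9 and 63.8). The 2 siRNAs had 54 and 32 (7.87 and 8.93), and GW8510 and siSRC4 had 54 and 172 (28.0 and 54.9). For GW8510 and siSRC2, 28 genes higher with the compound were lower with the siRNA (9 expected), and 38 the other way round (15.6 expected). An excess over either expectation is not by itself a shared effect. PD30 and both siRNA groups also lack the NC siRNA that the control carries, so agreement among these 3 cannot be separated from an effect of NC. Part of any agreement may still come from the shared controls, which were too few to split.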

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

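The direct tests between the siRNAs were chosen only after the result was seen. Of the 18 genes listed in opposite directions for siSRC2 and siSRC4, 17 differed between the siRNAs in a direct limma test at an adjusted p of 0.05, which choosing them by opposite calls nearly assures, and CRISPLD1 did not (adjusted p = 0.0716). ADAMTS19, a secreted metalloprotease, was 21.8 ± 4.02 with siSRC2 and 3.53 ± 0.849 with siSRC4 (9.17 ± 1.59 in the control), a log2 difference of -2.33 (siSRC4 minus siSRC2). The growth factor gene PDGFD differed by -1.02, the glutamate receptor gene GRIA4 by -1.23 and the unnamed gene ENSG00000285901 by -1.93. FOLR3, a folate receptor, was 3.05 ± 0.344 with siSRC2 and 15.7 ± 1.41 with siSRC4 (6.61 ± 0.182 in the control), a difference of 2.04. SGPL1, the sphingosine-1-phosphate lyase, differed by 1.60, the keratin-associated gene KRTAP2-3 by 1.57, ANKRD1, a YAP target, by 1.64 and ADAMTSL1 by 1.01. The level of KRTAP2-3 is uncertain because of near-identical relatives.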

How the results depend on the processing

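The splits of libraries, the counts at any fold, the directions without cell-cycle lists and those expected from GC content were chosen only after the data were seen. At a fold change of at least 2 the tables hold 1582 genes for PD30, 546 for GW8510, 52 for siSRC2 and 308 for siSRC4. At an adjusted p under 0.05 and any fold they imply 6171, 5816, 2020 and 3621. With a limma log2 difference of at least 1, the re-test passed 687, 183, 24 and 99 genes, and with a mean signal of at least 5 it passed 1329 for PD30 and 985 for GW8510, because fewer genes were tested. Among genes changed at least 2-fold in both comparisons, the share with the same direction was 38.5% of 13 for GW8510 with siSRC2, 65.0% of 40 for GW8510 with siSRC4 and 60% of 10 for the siRNAs, with intervals that include 50%, on fewer genes. At 2-fold, 1 list passed for GW8510 (3 tested), and with directions expected from GC content 1 list passed for siSRC4, the NRF2 targets, and the cause was not tested. For PD30 5 of 6 lists passed so, without the mitochondrially encoded genes. The other 117 values kept their direction and side of the threshold, or stayed within 1.5 times for counts. Leaving out each library gave 2127 to 2169 genes for PD30, 1450 to 1518 for GW8510, 286 to 292 for siSRC2 and 989 to 1106 for siSRC4. The log2 ratio of SRC ran from -0.84 to -0.77 with siSRC2 and from -0.94 to -0.79 with siSRC4. The share towards PD30 ran from 71.8% to 72.1% (GW8510), 80.4% to 81.7% (siSRC2) and 59.7% to 60.2% (siSRC4), and that of the same direction was 35.0% (GW8510 with siSRC2), 68.9% to 69.6% (GW8510 with siSRC4) and 79.8% to 80.8% (siRNAs). With the replicate block the re-test passed 2198, 1552, 302 and 1122 genes, and it moved no count by 1.5 times. The numbers of siSRC4 pair with the control by the rule for pairing. In siSRC2 too, every library correlated best with its own number, a hint from the data and not the design, and no such pattern held for PD30 or GW8510. In one fit over all groups, 21, 20, 21 and 20 of the 22 genes in all tables passed (21, 20, 21 and 19 in separate fits). Of the 10 splits of each 6 libraries 1, the real one, gave as many genes in the re-test: 2197 for PD30 (highest other 0), 1551 for GW8510 (3), 296 for siSRC2 (0) and 1096 for siSRC4 (0). With 10 splits a share under 0.05 cannot be reached. Other count normalizations, count-based tests, camera and the list test with a block were not run, since the tables hold normalized signals of called genes.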

Other observations

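The tests of the shared controls and of cell-cycle genes, and the GC comparison for siSRC4 with GW8510 and with PD30, were chosen only after the result was seen. Some genes outside the comparisons above moved in several groups, chosen here after their values were seen. HSP90AA1, a cytosolic chaperone, was 520 ± 35.7 in the PD45 control and lower at 280 ± 31.9 in PD30, 215 ± 32.8 with GW8510 and 312 ± 111 with siSRC4. CYP1B1, a target of the aryl hydrocarbon receptor, was higher with both siRNAs, at 5.66 ± 0.450 and 7.83 ± 2.15 against 3.16 ± 0.817. FABP4 and IL7R, an interleukin receptor, were lower in all 4 comparisons, with FABP4 at 90.6 ± 1.80 in the control and 23.0 ± 2.89 in PD30, and FGFR4, a fibroblast growth factor receptor, and HLA-DMA were listed as higher in all 4. ASNS, the asparagine synthetase, was 55.5 ± 3.48 in PD30 but 6.43 ± 0.919 with GW8510, against 14.4 ± 2.51 in the control.

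Lists of other cell types held at most 4 listed genes each. With GW8510, 4 of 10 smooth muscle and pericyte markers were listed, where 1.18 were expected (hypergeometric test, adjusted p = 0.122), with KCNJ8 and ABCC9 higher and RGS5 and LMOD1 lower. The pericyte marker RGS5 was lower in PD30 (1.53 ± 0.786), with GW8510 (3.32 ± 0.630) and with siSRC4 (6.44 ± 2.21), against 9.80 ± 1.93. Of 16 lung fibroblast markers 5 were listed for PD30, 4 higher and 1 lower. The lower one was S100A4, a calcium-binding protein of fibroblasts, at 94.2 ± 10.8 in PD30 and 448 ± 27.3 in the control. TEK, the angiopoietin receptor, was 29.7 ± 1.43 in PD30 and 12.5 ± 1.43 with siSRC2, against 7.39 ± 1.16. No immune marker was listed for PD30, siSRC2 or siSRC4, and 1, CD68, was lower with GW8510 (28.1 ± 2.84 against 48.0 ± 5.81).

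The direction of listed genes followed transcript GC content with siSRC4 and GW8510. The largest slope of any library on GC was 0.145 times that of the siSRC4 fold changes and 0.0764 times that of GW8510. These slopes come from listed genes, which were chosen for a small spread within groups. They can therefore not decide on a GC bias that varies between libraries. Around their group mean, the siSRC4 libraries had slopes of -0.0972, 0.0156 and 0.0816 per 10 points of GC. A GC bias shared by all libraries of a group cannot be told apart from the treatment, as the labels do not say whether groups were prepared apart, and the weaker end of the trend had 91.8% of siSRC4 genes and 75.7% of GW8510 genes in its direction. The same composition may account for the shared direction of GW8510 and siSRC4, which lay only 2.07 percentage points above the value expected within classes of GC content and length, and leaves open that of siSRC4 with PD30 (3.29 points above). A transcriptional response of AT-rich or GC-rich genes to either treatment stays possible and was not tested.

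Most genes shared by GW8510 and PD30 changed towards the PD30 level, and without cell-cycle and histone lists 70.9% still did, but these lists hold only 36 of the 606 genes, so that removal decides nothing about cell-cycle genes as the cause. The share lay 17.1 percentage points above that expected within classes of GC content and length (permutation p = 1e-04, the smallest possible with these permutations), so composition alone is argued against. The same excess was 24.9 points for siSRC2 with PD30 and 23.8 points for the 2 siRNAs (permutation p = 1e-04, the smallest possible), where PD30 and the siRNA groups all lack the NC siRNA of the control, which alone could give agreement. At an adjusted p under 0.01 in both, the lower end of the 95% interval of the share lay 7.85 percentage points above the bound. That bound counts the genes expected to be listed falsely and rests on the authors' p-values. It leaves out that shared control noise helps agreeing genes past the fold threshold in both comparisons. It can therefore not decide whether noise of the shared controls is the whole cause. A partial return to the younger state stays open and untested, and the PD30 difference itself holds the NC siRNA, in which GW8510 and its control do not differ. By the labels, GW8510 and its control differ in DMSO as well as in the compound.

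GW8510 and siSRC2 moved shared genes in opposite directions. Noise of the shared controls gives agreement and is no explanation of opposite directions. The opposite share lay 8.25 percentage points above that expected from GC content and transcript length (permutation p = 0.0506), so composition may account for it and cannot be told apart from a treatment effect on 103 genes. With the length of the gene span in place of the transcript the difference was 9.64 points (permutation p = 0.0237). Both of these p-values are one-sided. No biological explanation was tested.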
